A study of Mus musculus with 4 samples.

How the data were processed

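Droplet-based single-cell RNA sequencing (10x Genomics 3′ chemistry, in which each captured molecule carries a unique molecular identifier, UMI) was performed on the ascending aorta of male wild-type mice with an aortic dissection model. The 4 libraries form 2 groups taken from the sample labels: mice with the dissection model alone (AD, 2 libraries) and mice with the model that also received paquinimod (AD_ABR, 2 libraries). Each library was deposited as a matrix of UMI counts per gene and cell barcode, and the values were whole numbers without normalization, per the file headers. Reads were aligned with STAR and counted with Cell Ranger 6.0 against GRCm38, with Seurat 4.0 used downstream, per the submitters' processing notes, whereas the matrices name Cell Ranger 7.1.0, per the file headers. The order of these tools, the annotation release used for counting and any filter applied by the authors after barcode calling were not given in the sources used here. Gene symbols and identifiers were those in the deposited files, and coordinates came from GENCODE mouse release M21 on GRCm38, which held 52081 of the 55357 gene identifiers. The files gave 79 symbols to more than 1 identifier, and these genes were kept apart by identifier. The 3′ reads do not separate overlapping genes on the same strand or near-identical copies, and Rn18s-rs5, a sequence related to ribosomal RNA that had no entry in the annotation used for coordinates, is given as a property of the libraries.

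Barcodes were kept with at least 200 detected genes and a mitochondrial share of UMIs below 20%. Doublets were scored in each library with Scrublet (scanpy 1.11.5, random seed 1), and the barcodes with the highest scores were removed up to an expected rate of 0.8% per 1000 barcodes. This removed 791 and 916 barcodes from the AD libraries and 665 and 934 from the AD_ABR libraries. The caller's own threshold would have marked 130 and 290 barcodes (1.31 and 2.71%) in AD and 268 and 520 (2.94 and 4.81%) in AD_ABR. Removed before that step were 14 and 14 barcodes in AD and 1 and 4 in AD_ABR for too few genes. For a high mitochondrial share 121 and 463 were removed in AD and 113 and 132 in AD_ABR. A barcode that failed both filters is in both counts. Counts of the kept cells were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, chosen over the libraries among genes seen in at least 10 cells, were scaled with values clipped at 10 and reduced to 30 principal components. A shared-nearest-neighbour graph on 15 neighbours was partitioned by the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0, without integration of the libraries, which gave 32 clusters. The files carry no cell annotation used here, so classes were rebuilt from 25 fixed marker lists and are called by the type whose markers they express with the ending -like. A cluster took a class name where at least 3 markers of that class were detected in at least 10% of its cells and their mean log2 fold over all other cells, with 5 CPM added (CPM is a gene's UMI count scaled by the summed UMIs in edgeR's usual unit), was at least 1. It stayed without a name, and is called by its number, where its 10 leading genes held more markers of another type or where its cells were shallow and none of the markers led. Names rebuilt in this way may differ from those the authors gave.

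For tests between groups, UMI counts were summed per library over all kept cells and over the cells of each class or unnamed cluster that had at least 50 cells in each library, since cells are not replicates. Sums were tested with edgeR 4.0.16 in R 4.3.3 as AD_ABR minus AD, with TMM normalization, the filterByExpr filter on low counts, robust dispersion estimates, glmQLFit and the quasi-likelihood F test, and with Benjamini-Hochberg adjustment over the genes tested in that class at a threshold of 0.05. Adjusted p-values of genes and shares throughout come from edgeR in this form. Standard errors of log2 fold changes were obtained as the fold change divided by the square root of F. Levels are given as CPM of the summed counts, with the SD over 2 libraries. Sets of genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, for 23 fixed lists where at least 5 members passed the filter, with Benjamini-Hochberg adjustment over the lists of a class. Each list was also tested with the correlation estimated from the data and with fry. For each list the numbers of members past the edgeR test over all genes and past the threshold when adjusted over the list alone are given. Class shares were tested for classes with at least 10 cells in each library, by the edgeR quasi-likelihood test on numbers of cells with all kept cells as library size, adjusted over the 18 classes and clusters tested. An exact two-sided permutation test of each share was run beside it; with 2 libraries against 2 there are 6 arrangements and the smallest p is 0.333. Intervals of shares are exact 95% binomial (Clopper-Pearson) intervals, a count of 0 was set against a floor of 3 counts, and ratios of sums with few counts carry exact 95% intervals. These intervals and floors cover counting error only.

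Genes of one cell type appear at low counts in others through free RNA in the suspension. A gene was called prone to this in a class where its CPM was under 0.1 of its level in the class or cluster with the highest level. Shares of cells with an S100a8 UMI are given beside those of smooth muscle-like, fibroblast-like and endothelial-like cells, and again after thinning each cell to 1000 UMIs with shallower cells left out. The test, the samples, the cell filters, the marker and gene lists and most of the alternatives were chosen before the data were examined. Named genes followed a rule fixed at the same point. In each tested class these were up to 10 genes per direction with the largest fold among those past the threshold, with both AD_ABR libraries on the same side of both AD libraries, a mean CPM of at least 20 and no role as a marker of another class. Some genes that this rule picks are not reported here. Where fewer than 5 genes passed in a direction, up to 5 genes with the smallest p were given as values. S100a8 and S100a9 were added in each tested class, as were up to 4 members of each described list with the largest fold among those with a mean CPM of at least 20. Markers of other cell types were named where they moved with a group.

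The tests were checked on simulated counts drawn from gene means pooled over the libraries, the dispersion trend and the library sizes of each class. In each class 200 genes were changed 2-fold or 4-fold. The spread of single genes around that trend and shifts in cell make-up were not simulated. The share of changed genes recovered at 2-fold and at 4-fold was 39 and 83% for all cells summed, 76 and 93% for smooth muscle-like, 57 and 92% for endothelial-like, 62 and 91% for fibroblast-like, 30 and 84% for macrophage-like, 35 and 82% for dendritic-like and 16 and 75% for Schwann-like cells. Unchanged genes were called at rates from 0.015% for all cells summed to 0.204% for Schwann-like cells. In each of these comparisons, 20 of 20 sets of 20 genes shifted 1.5-fold and 0 of 20 unchanged sets passed camera, with genes drawn independently of each other. For shares, 50 simulated rounds with 3 of 18 classes changed 8-fold recovered 72.7% of the changed classes and called 0.93% of the unchanged ones.

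Alternatives covered RLE size factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, each library left out in turn, doublets kept, at least 500 genes per cell, a mitochondrial share below 10%, Leiden resolutions of 0.5 and 2.0, clustering without the genes of the fixed lists, classes from single-cell marker scores and TMM factors over classes. Leaving out genes prone to free RNA, tests of unnamed clusters and of cluster 10 alone, and a crossed pairing were added after the data had been seen. Replicates of a group were compared by a chi-square test of their summed counts over genes with at least 20 UMIs. Clustering and resampling used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and pandas 2.3.3, with 10000 bootstrap draws and 100000 permutations for comparisons of gene lists. These draws and permutations were taken over genes, so the intervals of list medians and the permutation p-values between lists hold no spread between libraries.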

Results

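The ascending aorta was profiled by single-cell RNA sequencing in a mouse model of aortic dissection, to ask how paquinimod, a small molecule that binds S100A9, changes the cells of the diseased vessel. Dissection was induced in male wild-type mice from 3 weeks of age with β-aminopropionitrile (BAPN), an inhibitor of the lysyl oxidases that cross-link collagen and elastin, given in drinking water at 1 g/kg per day for 4 weeks. Mice of the AD group received BAPN alone (2 libraries), and mice of the AD_ABR group also received paquinimod by gavage at 10 mg/kg per day (2 libraries). The libraries held 76142840 and 99572008 UMIs over 10069 and 11161 barcodes in AD, and 93575616 and 98946432 UMIs over 9230 and 10939 barcodes in AD_ABR. After filtering, 37259 cells remained, 9154 and 9782 in AD and 8451 and 9872 in AD_ABR. The kept AD_ABR cells held a median of 9452 and 8208 UMIs per cell, against 5268 and 7185 in AD. Rn18s-rs5, a sequence related to ribosomal RNA, took 5.34 and 3.23% of the UMIs of kept cells in AD and 1.83 and 1.37% in AD_ABR. Summed counts differed beyond sampling noise between the replicates of AD (chi-square per degree of freedom of 151) and of AD_ABR (69.7), and by more between libraries of different groups (208 to 487). The labels do not say whether replicates came from separate animals, so p-values of genes and shares measure only the spread between these libraries.

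Neutrophil-like cells, the main source of S100A8 and S100A9, were 57.8-fold less frequent in AD_ABR. They made up 10.1% ± 10.9 of cells in AD (17.9 and 2.37%) and 0.175% ± 0.104 in AD_ABR (0.248 and 0.101%; SD, n = 2; log2 fold change −5.85 ± 0.90 SE, adjusted p = 2.53e-06). The size of this fall rests on AD replicate 1, without which the log2 fold change was −3.77 (adjusted p = 0.000391). B-like cells fell from 3.47% ± 2.03 to 0.321% ± 0.119 (10.7-fold, adjusted p = 0.00118), dendritic-like cells from 6.14% ± 0.602 to 1.36% ± 0.345 (4.52-fold, adjusted p = 0.016) and T-like cells from 2.82% ± 1.45 to 0.666% ± 0.29 (4.21-fold, adjusted p = 0.0195). Proliferating cells fell 5.81-fold, from 3.92% ± 0.244 to 0.673% ± 0.165 (adjusted p = 0.0092), and lymphatic endothelial-like cells fell 7.18-fold, from 2.52% ± 1.22 to 0.351% ± 0.123 (adjusted p = 0.00511). These 6 of the 12 named classes tested were lower in both AD_ABR libraries than in both AD libraries, and 0 named classes rose by edgeR. With TMM factors over classes the dendritic-like (log2 fold change −1.69, adjusted p = 0.0876), T-like (−1.48, 0.114), lymphatic endothelial-like (−2.18, 0.055) and proliferating calls (−2.06, 0.0582) were lost. Smooth muscle-like cells, the contractile cells of the aortic media, were 16.4% ± 8.77 of cells in AD and 36% ± 9.69 in AD_ABR, which did not pass the test (adjusted p = 0.174). Macrophage-like cells (7.26% ± 5.49 and 5.46% ± 2.42, adjusted p = 0.642) and fibroblast-like cells (14.8% ± 7.43 and 17.7% ± 5.37, adjusted p = 0.721) did not pass. Endothelial-like cells (3.54% ± 1.91 and 2.80% ± 0.0216, adjusted p = 0.68), Schwann-like cells (0.740% ± 0.266 and 1.55% ± 0.68, adjusted p = 0.202) and pericyte-like cells (0.250% ± 0.168 and 0.160% ± 0.0252, adjusted p = 0.502) did not differ past the threshold either. The macrophage-like class leaves out cluster 6, whose best marker list was that of macrophages but which stayed unnamed. Cluster 6 made up 8.40 and 6.45% of AD and 1.51 and 2.57% of AD_ABR (adjusted p = 0.0297), and as 4 of its 10 leading genes fell within it, this is not read as a change in a cell type. Of the unnamed clusters tested, cluster 2 rose 4.73-fold, from 3.45% ± 2.07 to 16.4% ± 1.66 (adjusted p = 0.016), and cluster 21 rose 4.76-fold, from 0.359% ± 0.233 to 1.72% ± 1.34 (adjusted p = 0.016). The best marker list of cluster 2 was that of fibroblasts, but its leading genes held more pericyte markers, so the fibroblast-like class leaves it out. Clustered without list genes, fibroblast-like cells numbered 1370 and 2769 in AD and 3026 and 4531 in AD_ABR. At Leiden resolution 0.5 they numbered 854 and 1841 against 472 and 1110. The fibroblast-like share did not pass by edgeR in either setting. Cluster 15 fell 4.12-fold, from 3.95% ± 2.75 to 0.960% ± 0.283 (adjusted p = 0.0195). These 4 cluster calls were lost without AD_ABR replicate 1 (share of cells, cluster 2, adjusted p = 0.152; share of cells, cluster 21, 0.431; share of cells, cluster 15, 0.211; share of cells, cluster 6, 0.328) or replicate 2 (0.127, 0.0756, 0.262 and 0.142). The cluster 15 call was also lost without AD replicate 2 (0.14) and with TMM factors (0.0876), and the cluster 6 call with TMM factors (0.136). Without AD replicate 2 the rises of smooth muscle-like cells (log2 fold change 1.81, adjusted p = 0.0293) and cluster 14 (share of cells, cluster 14, 1.88, 0.0293) passed. Chondrocyte-like cells, a cartilage type with fewer than 10 cells in 1 library, made up 3.04 and 1.85% of AD and 0.343 and 0.0709% of AD_ABR. Cluster 13, led by Cxcl5 and Lif and untested for the same reason, made up 4.48 and 5.78% of AD and 0.592 and 0.0810% of AD_ABR. When clustered without list genes, 75.8% of its cells and 90.7% of those of cluster 15 joined 1 cluster, at 5.75 and 12% of AD and 1.04 and 1.04% of AD_ABR. Cells of cluster 26, led by Ttn, Cited4 and Il7r, numbered 104 and 1 in AD and 0 and 0 in AD_ABR, where 0 cells allow shares of up to 0.0355 and 0.0304%. Mesothelial-like cells, also too few to test, went the other way, with 0 and 1 cells in AD and 15 and 14 in AD_ABR. The smallest exact permutation p that 2 libraries against 2 allow, 0.333, was reached by each of the 6 lower classes. Without AD_ABR replicate 1 or replicate 2 the calls were lost for B-like (adjusted p = 0.149 and 0.0756), dendritic-like (0.296 and 0.127), T-like (0.328 and 0.127), proliferating (0.211 and 0.127) and lymphatic endothelial-like cells (0.149 and 0.127). The neutrophil-like call was kept (0.0083 and 0.029). Without AD replicate 1 the T-like call was lost (0.0651).

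**Figure D1:**
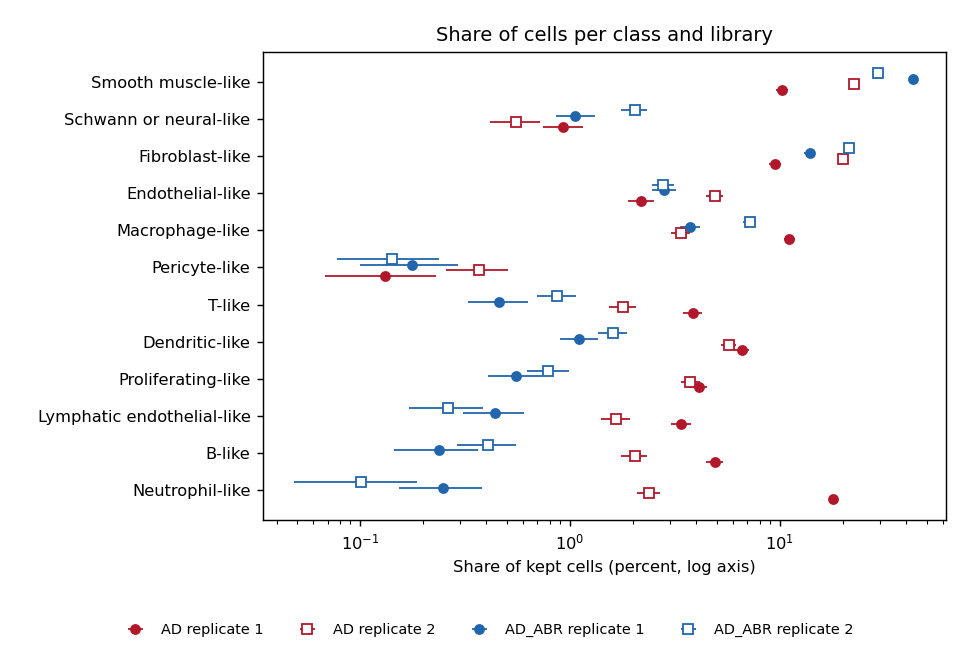
Share of kept cells (percent, log axis) in each class for the 4 libraries, coloured by group, with exact 95% binomial intervals that cover counting error only. Neutrophil-like cells run from 17.9 and 2.37% in AD to 0.248 and 0.101% in AD_ABR.

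S100a8 (chromosome 3, 90668978 to 90670035) and S100a9 (chromosome 3, 90692632 to 90695721; GRCm38), the genes of the calcium-binding proteins that paquinimod targets, were transcribed mainly in neutrophil-like cells. This class held 90.9 and 90.6% of the S100a8 UMIs of the AD libraries and 91.8 and 71.6% of those of AD_ABR, and 90.3 and 92.8% against 90.7 and 85.0% of the S100a9 UMIs. Within the class, 90.8 and 87.1% of cells in AD and 90.5 and 80.0% in AD_ABR carried an S100a8 UMI, the latter from 21 and 10 cells. Over all cells summed, S100a8 stood at 381 ± 471 CPM in AD and 5.15 ± 5.43 CPM in AD_ABR (SD, n = 2; adjusted p = 0.0866), and S100a9 at 360 ± 428 and 6.78 ± 4.95 CPM (adjusted p = 0.074), neither past the test. Without AD replicate 2 both passed (adjusted p = 0.0181 and 0.00897), and the summed S100a8 count of the AD libraries was 50034 and 4198. In macrophage-like cells the S100a8 count was 203 and 53 UMIs in AD against 2 and 1 in AD_ABR, a ratio of 85.9 (95% interval 29.1 to 419, adjusted p = 0.03), and the S100a9 ratio was 124 (34.1 to 1030, adjusted p = 0.03). Both calls were lost without AD_ABR replicate 1 (0.233 and 0.255) or replicate 2 (0.796 and 0.718). An S100a8 UMI was seen in 14.8 and 1.52% of macrophage-like cells in AD and in 0.631 and 0.141% in AD_ABR, at median depths of 4286, 4672, 6666 and 5725 UMIs. In smooth muscle-like cells the share was 13.3 and 1.04% against 0.304 and 0.243%, at 8035, 7499.5, 10538 and 9436 UMIs. The fibroblast-like share was 17.2 and 1.48% against 0.256 and 0.283%, and the endothelial-like share 16.5 and 0.628% against 0.840 and 0.364%. After thinning to 1000 UMIs the share was 3.58 and 0.990% in AD and 0.645 and 0.0% in AD_ABR for macrophage-like cells. It was 2.52 and 0.245% against 0.0564 and 0.140% for smooth muscle-like and 3.12 and 0.102% against 0.0 and 0.0% for fibroblast-like cells. For endothelial-like cells it was 4.57 and 0.0% against 0.424 and 0.0%. In AD replicate 2, 81.1% of the S100a8 UMIs of macrophage-like cells came from 1 cell. S100a8 and S100a9 did not pass in smooth muscle-like (adjusted p = 0.303 and 0.364), endothelial-like (0.681 and 0.734), fibroblast-like (0.252 and 0.34) or dendritic-like cells (0.761 and 0.737).

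**Figure D2:**
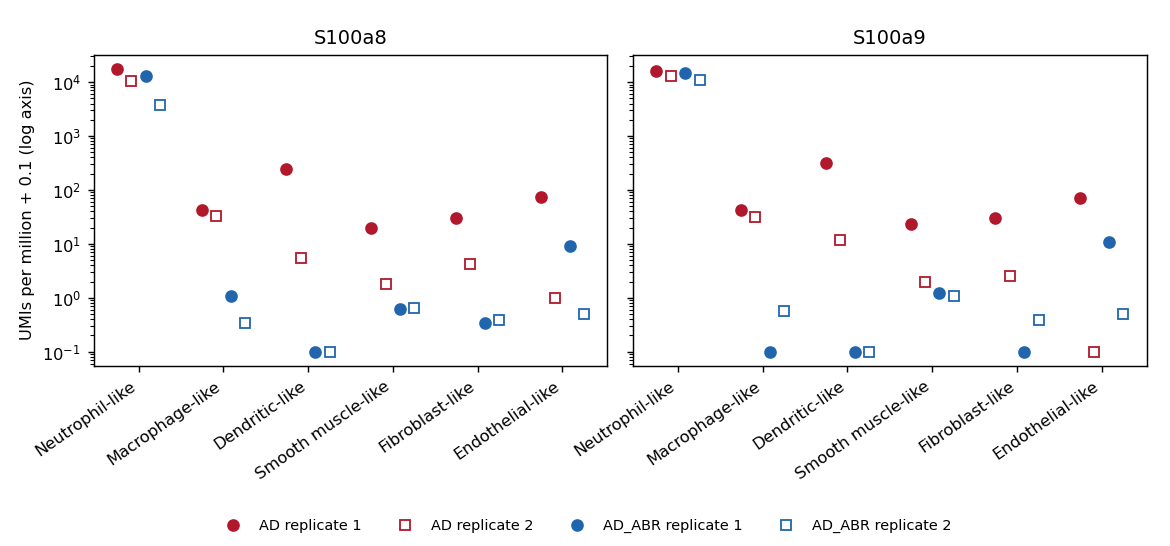
Level of S100a8 and S100a9 (CPM plus 0.1, log axis) in 6 cell classes, with a point for each of the 4 libraries coloured by group. Levels are highest in neutrophil-like cells, and the AD points of the other classes lie well below them.

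In smooth muscle-like cells Klf15 and Zbtb16 rose in AD_ABR, and Idi1, Insig1, Scd2 and Cxcl2 fell. Klf15, a transcription factor of the muscle response to glucocorticoids (chromosome 6, 90462576 to 90475238), rose from 12.6 ± 0.354 to 46.3 ± 8.58 CPM (SD, n = 2; log2 fold change 1.87 ± 0.15 SE, adjusted p = 7.76e-07). Zbtb16, a zinc finger gene of the same response (chromosome 9, 48654297 to 48836222), rose from 54.6 ± 1.52 to 143 ± 8.51 CPM (1.39 ± 0.12 SE, adjusted p = 8.28e-07). Mthfd2, Fam124a, Ahsa2, Ntn4, Haus8, Myoz2 and Foxs1 rose by log2 fold changes of 1.15 to 1.66. The sterol-regulated genes Idi1, an isomerase of sterol synthesis (46.0 ± 7.89 to 16.6 ± 3.11 CPM, log2 fold change −1.45, adjusted p = 1.49e-05), and Insig1 (36.3 ± 3.4 to 14.2 ± 2.25 CPM, −1.34, adjusted p = 5.42e-06) fell. The desaturase gene Scd2 fell from 85.1 ± 17.2 to 27 ± 4.69 CPM (−1.64, adjusted p = 1.31e-05). The neutrophil-attracting chemokine gene Cxcl2 fell from 34.0 ± 1.36 to 13.8 ± 0.698 CPM (−1.29, adjusted p = 3.09e-06), and stood at 0.0012 of its level in neutrophil-like cells. Malt1, Hmox1 and Tent5a also fell, by log2 fold changes of −1.50, −1.27 and −1.24. Rn18s-rs5 and Lars2, signs of ribosomal RNA in a library, moved with these genes, at log2 fold changes of −1.43 and −1.31. Of 14877 genes tested, 1111 rose and 1395 fell in sums of 7.64 to 39.1 × 1e+06 UMIs. The number of changed genes, 2506, was 1548 without AD replicate 1, 1015 without AD_ABR replicate 2 and 1524 by DESeq2. The class joins clusters 0, 3 and 8. Cluster 8, led by Tnnt2, Corin and Des, scored highest on the list for cardiac or skeletal muscle, with only 2 markers of it detected, and held 233 of 937 and 667 of 2214 cells in AD and 377 of 3623 and 283 of 2879 in AD_ABR.

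Among the fixed gene lists, targets of the inflammatory transcription factor NF-kB had the lowest camera p-value in smooth muscle-like cells, and they fell. Of 20 NF-kB targets 16 fell (18 when adjusted over the list alone) and 0 rose, with a median log2 fold change of −1.02 (camera adjusted p = 9.54e-20, and adjusted p = 0.214 with an estimated correlation). Rel fell from 29.7 ± 0.282 to 12.8 ± 1.19 CPM, Ptgs2, the inducible cyclooxygenase, from 103 ± 22.3 to 46.1 ± 3.93 CPM, and the adhesion molecule Vcam1 from 48.5 ± 4.85 to 24.1 ± 0.324 CPM. Of 24 cytokine and chemokine genes 15 fell and 1 rose (19 and 1 adjusted over the list alone; median −1.28, adjusted p = 6.81e-18, and 0.229 with an estimated correlation), with Cxcl1 at −1.05 and Cxcl12 at −0.83. In this class 16 of the 20 NF-kB targets and 23 of the 24 cytokine genes were prone to free RNA from other cells. Unfolded protein response genes rose, 8 of 17 against 1 that fell (11 and 1 adjusted over the list alone; median 0.41, adjusted p = 6.05e-07, and 0.229 with an estimated correlation), with Manf at 0.92, Creld2 at 0.77 and the transcription factor Xbp1 at 0.73. Of 23 oxidative phosphorylation genes 4 rose (5 adjusted over the list alone; median 0.23, adjusted p = 0.000361, and 0.534 with an estimated correlation), led by Sdhb and Atp5g1. The contractile list did not pass (median 0.10, camera adjusted p = 0.332). Of 19 members 2 were higher and 1 lower (3 and 2 adjusted over the list alone). Among them were Tagln (log2 fold change 0.51, adjusted p = 0.0228) and Des (−0.42, adjusted p = 0.0235). Des is a leading gene of cluster 8, a smaller part of this class in AD_ABR, and its fall was not tested apart from that. Several other lists fell with most of their members prone to free RNA. Of 22 cell cycle genes, 20 of them prone, 12 fell and 1 rose (15 and 1 adjusted over the list alone; median −0.96, adjusted p = 6e-07, and 0.229 with an estimated correlation). Of 9 MHC class II genes, all prone, 4 fell (5 adjusted over the list alone; −0.73, adjusted p = 0.000821, and 0.337 with an estimated correlation). Of 15 endothelial activation genes, 13 prone, 6 fell (8 adjusted over the list alone; −0.43, adjusted p = 0.000361, and 0.229 with an estimated correlation). Of 19 interferon response genes, 13 prone, 6 fell and 1 rose (8 and 1 adjusted over the list alone; −0.42, adjusted p = 0.000821, and 0.229 with an estimated correlation). Of 5 T cell activation genes, all prone, 3 fell (4 adjusted over the list alone; −1.97, adjusted p = 0.000671, and 0.337 with an estimated correlation). Matrix proteases and inhibitors (median −0.30, 9 of 20 fell and 1 rose, 10 and 1 adjusted over the list alone, adjusted p = 0.00233, and 0.293 with an estimated correlation) included Timp1 at −1.03 and Adamts1 at −0.55. A further 3 lists passed with all libraries but not without AD replicate 2. They were synthetic phenotype genes (−0.30, 6 of 20 fell and 3 rose, 8 and 3 adjusted over the list alone, adjusted p = 0.0253, and 0.15 without that library) and dissociation stress genes (−0.13, 8 of 22 fell and 2 rose, the same adjusted over the list alone, 0.00747, and 0.156 without it). The other was the inflammasome list (−0.34, 3 of 9 fell and 1 rose, 4 and 1 adjusted over the list alone, 0.0378, and 0.078 without it, or 0.0856 without AD_ABR replicate 1). With an estimated correlation their adjusted p were 0.327, 0.534 and 0.337. The lists of collagens and elastic fibre (median −0.03, adjusted p = 0.383), TGF-beta response (−0.04, 0.295), glycolysis and hypoxia (−0.06, 0.332), and oxidative stress (0.13, tested downward, 0.929) did not pass. Nor did those of apoptosis and p53 (−0.09, 0.509), mitochondrially encoded genes (0.11, 0.121), S100 alarmins and receptors (−0.01, tested upward, 0.477), resident macrophage genes (−0.35, 0.158) or neutrophil granule genes (−2.57, 0.0811).

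Endothelial-like cells expressed less Sele, Selp and Icam1, which encode adhesion molecules for leukocytes, in AD_ABR. Sele, which encodes E-selectin (chromosome 1, 164048234 to 164057677), fell from 355 ± 0.474 to 53.6 ± 19.0 CPM (SD, n = 2; log2 fold change −2.72 ± 0.20 SE, adjusted p = 2.73e-05). Selp, which encodes P-selectin, fell from 646 ± 63.1 to 249 ± 24.9 CPM (−1.38 ± 0.14 SE, adjusted p = 0.000155), and Icam1 from 1261 ± 106 to 566 ± 23.2 CPM (−1.16 ± 0.13 SE, adjusted p = 0.000275). Endothelial activation genes fell as a list, 5 of 16 with 0 that rose (8 and 1 adjusted over the list alone; median −0.34, camera adjusted p = 9.13e-07, and adjusted p = 0.195 with an estimated correlation). NF-kB targets fell in 14 of 20 cases (18 adjusted over the list alone; median −1.07, adjusted p = 3.25e-28, and 0.136 with an estimated correlation), with 6 of the 20 prone to free RNA. Tnfaip3, a brake on NF-kB signalling, fell from 120 ± 9.47 to 29.2 ± 7.71 CPM (−2.02 ± 0.19 SE, adjusted p = 7.44e-05), Rel by a log2 fold change of −1.92 and the monocyte attractant Ccl2 by −2.24. Of 16 cytokine genes 5 fell (7 adjusted over the list alone; median −0.78, adjusted p = 2.36e-08, and 0.195 with an estimated correlation). Dissociation stress genes, which respond to the preparation of cells, also fell, 11 of 22 (18 adjusted over the list alone; median −0.79, adjusted p = 9.58e-19, and 0.195 with an estimated correlation), with Atf3 at −1.39 and Zfp36 at −1.42. Ankrd1, Cdh11, Noct, Map3k8 and Tifa fell by log2 fold changes of −3.68 to −1.86. The Noct call was lost without AD_ABR replicate 1 or 2 (adjusted p = 0.176 and 0.221). The glucocorticoid-induced gene Zbtb16 rose from 21.5 ± 3.26 to 78.9 ± 9.08 CPM (log2 fold change 1.85 ± 0.19 SE, adjusted p = 0.000155). Fkbp5 rose too (1.57 ± 0.25 SE, adjusted p = 0.00264, and 0.102 without AD_ABR replicate 2), as did the sulfotransferase gene Sult1a1 (1.95, adjusted p = 0.000419, but −0.02 with doublets kept), Fmo2 and Gdf6. Unfolded protein response genes rose, 6 of 17 against 1 that fell (9 and 1 adjusted over the list alone; median 0.41, adjusted p = 2.34e-05, and 0.195 with an estimated correlation). Rn18s-rs5 fell with these groups, at a log2 fold change of −1.39. Of 10762 genes tested, 164 rose and 433 fell. The 597 changed genes were 960 without AD replicate 1, 1870 without AD replicate 2, 138 without AD_ABR replicate 1, 67 without AD_ABR replicate 2 and 324 by DESeq2.

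**Figure D3:**
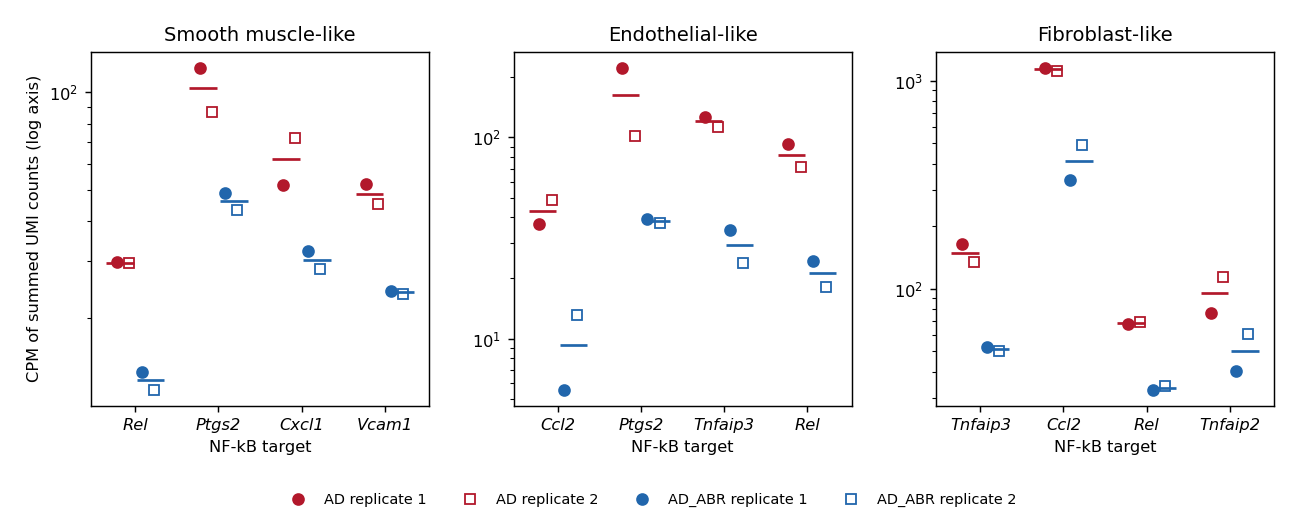
Level (CPM) of 4 NF-kB targets each in smooth muscle-like, endothelial-like and fibroblast-like cells, with a point for each library and a line at the mean of each group. The 4 are the members with the largest fold change in that class at a mean CPM of at least 20, so the genes may differ between panels. In endothelial-like cells Tnfaip3 stands at 120 CPM in AD and 29.2 CPM in AD_ABR on average.

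Fibroblast-like cells showed lower chemokine genes and higher Fkbp5 and Tsc22d3 in AD_ABR. The interferon-induced chemokine gene Cxcl10 fell from 292 ± 8.43 to 72.9 ± 22.3 CPM (SD, n = 2; log2 fold change −2.0 ± 0.21 SE, adjusted p = 0.0179). Ccl2 fell from 1133 ± 28.2 to 412 ± 110 CPM (−1.46 ± 0.20 SE, adjusted p = 0.0286) and Cxcl2 from 484 ± 54.2 to 136 ± 38.0 CPM (−1.83 ± 0.21 SE, adjusted p = 0.0199). Tnfaip3 fell from 149 ± 22 to 51.2 ± 1.57 CPM (−1.54 ± 0.14 SE, adjusted p = 0.00658) and Cxcl5 by a log2 fold change of −1.72 (adjusted p = 0.00658). Of 20 NF-kB targets 4 fell (15 adjusted over the list alone; median −0.69, camera adjusted p = 2.87e-20, and adjusted p = 0.267 with an estimated correlation), with 5 prone to free RNA. Of 24 cytokine genes 6 fell (12 adjusted over the list alone), with a median of −0.99 (camera adjusted p = 2.57e-20, and 0.267 with an estimated correlation). Of the 24 genes 14 were prone, Cxcl2 and Cxcl10 among them, each under 0.1 of its highest level elsewhere. Fkbp5 rose from 39.7 ± 7.07 to 101 ± 11.2 CPM (1.33 ± 0.15 SE, adjusted p = 0.0179) and Tsc22d3, the glucocorticoid-induced leucine zipper gene, from 142 ± 14.9 to 392 ± 105 CPM (1.47 ± 0.20 SE, adjusted p = 0.031). Ntf3, Sult1a1, Dpep1 and Rasl11a rose by log2 fold changes of 1.27 to 1.72. Unfolded protein response genes had a median of 0.40 (adjusted p = 5.49e-08, and 0.431 with an estimated correlation), with 7 of 17 that rose when adjusted over the list alone and 0 over all genes. The class joins clusters 1, 7 and 23, the last of which scored highest on the adipocyte list with 0 of its markers detected. Of 14568 genes tested, 32 rose and 54 fell. The 86 changed genes were 136 and 525 without AD replicate 1 and 2, 394 and 201 without AD_ABR replicate 1 and 2, and 302 by DESeq2. The Cxcl10, Ccl2, Cxcl2 and Tsc22d3 calls were lost without AD replicate 1 (0.153, 0.145, 0.104 and 0.146) or AD replicate 2 (0.0738, 0.068, 0.0645 and 0.0888).

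**Figure D4:**
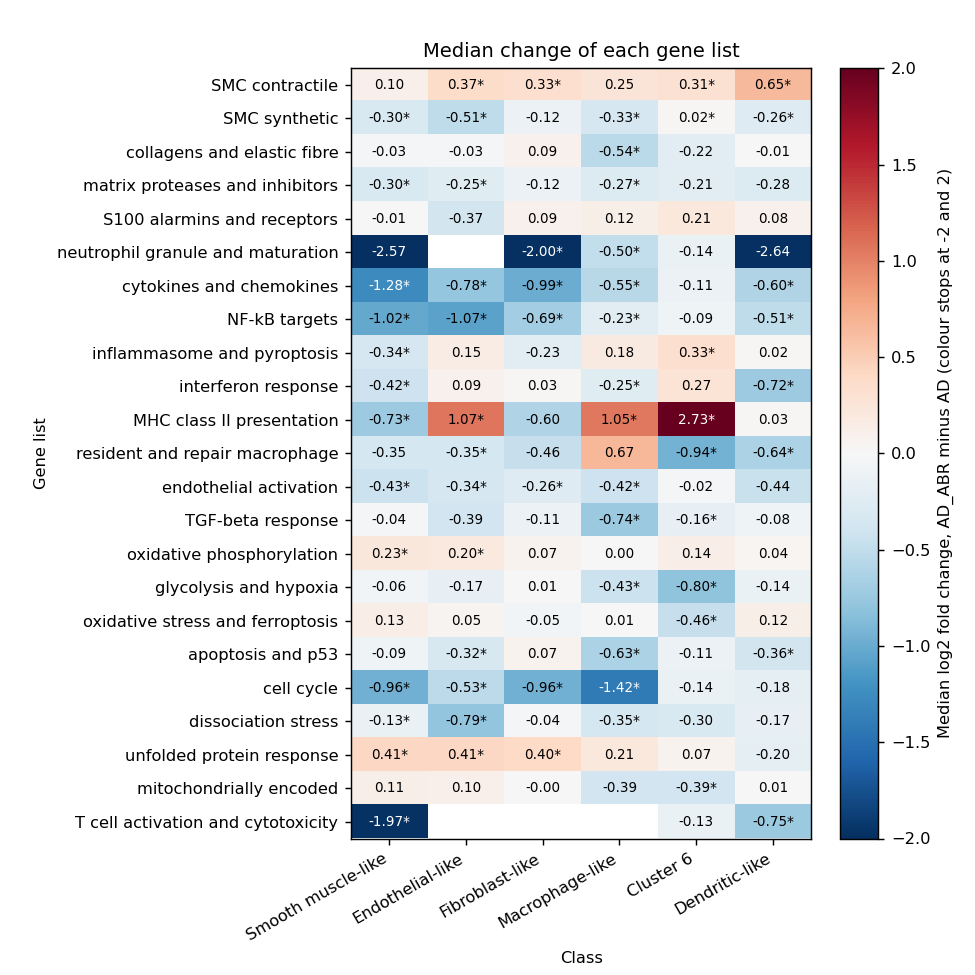
Median log2 fold change (AD_ABR minus AD) of each fixed gene list in 6 classes, with the colour scale ending at 2 in either direction and a star where the camera adjusted p at the preset correlation was below 0.05. NF-kB targets have medians of −1.02, −1.07 and −0.69 in smooth muscle-like, endothelial-like and fibroblast-like cells.

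In macrophage-like cells the adhesion gene Jaml (chromosome 9, 45079183 to 45108534) rose from 5.13 ± 0.188 to 262 ± 53.4 CPM (SD, n = 2; log2 fold change 5.65 ± 0.27 SE, adjusted p = 0.00339, and 0.0678 without AD_ABR replicate 2). It was the 1 gene that rose among 10756 tested, and the 2 that fell were S100a8 and S100a9, both prone to free RNA at 0.0012 of their level in neutrophil-like cells. MHC class II genes rose as a list (median 1.05, camera adjusted p = 1.67e-06, and adjusted p = 0.314 with an estimated correlation), with 6 of 9 members that rose when adjusted over the list alone and 0 over all genes. H2-Eb1 stood at 1536 ± 570 CPM in AD and 3842 ± 75.6 CPM in AD_ABR. Cell cycle genes fell as a list (median −1.42, adjusted p = 1.6e-13, and 0.26 with an estimated correlation), with 12 of 18 past the threshold adjusted over the list alone, 0 over all genes and 11 prone to free RNA. Ifnb1 (316 ± 30.5 and 76.1 ± 3.48 CPM, log2 fold change −2.05, adjusted p = 0.0518), Ch25h (−2.88, adjusted p = 0.0518) and Ly96, a co-receptor of TLR4 (1.66, adjusted p = 0.0962), did not pass. Cluster 12, led by Cd72, Ms4a7 and Cx3cr1, held 91.8 and 28.2% of the class in AD, and cluster 10, led by Folr2, Cd163 and F13a1, held 92.4 and 92.4% in AD_ABR. The 3 changed genes were 781 without AD replicate 1, 3475 without AD replicate 2, 1 and 0 without AD_ABR replicate 1 and 2, and 209 by DESeq2, with 1678 at an unadjusted p below 0.05 with all libraries.

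Dendritic-like cells expressed more of the lysozyme gene Lyz2 in AD_ABR, 1846 ± 102 against 398 ± 13.4 CPM (SD, n = 2; log2 fold change 2.21 ± 0.18 SE, adjusted p = 3.98e-05). They expressed less Tnfsf4, the ligand of the T cell co-stimulator OX40, 8.34 ± 7.48 against 120 ± 24.6 CPM (−3.99 ± 0.44 SE, adjusted p = 0.0043). AA467197 (−2.59, adjusted p = 3.98e-05) and Spp1 (−1.77, adjusted p = 0.0048) fell, and Xlr (3.18, adjusted p = 0.0021) and Sult1a1 (4.02, adjusted p = 0.0196) rose. Of 20 NF-kB targets 4 fell (10 adjusted over the list alone; median −0.51, camera adjusted p = 1.37e-06, and adjusted p = 0.696 with an estimated correlation). Rn18s-rs5 and Lars2 fell by log2 fold changes of −2.15 and −1.70. Of 9384 genes tested, 53 rose and 86 fell, and these 139 became 752 without AD replicate 2, 353 without AD_ABR replicate 1 and 43 without AD_ABR replicate 2. In Schwann-like cells the melanocyte genes Dct (385 and 196 UMIs in AD, 0 and 0 in AD_ABR, at least 600-fold lower, adjusted p = 0.00121) and Mlana (at least 43.4-fold lower, adjusted p = 0.0276) fell. Pmel (ratio 127, 95% interval 21.6 to 5140, adjusted p = 0.00586), Ptgds (ratio 75.9, 19.9 to 645) and Syt4 (log2 fold change −4.83) also fell. Cells of cluster 27 with at least 3 melanocyte genes numbered 5 of 28 and 3 of 20 in AD and 0 of 12 and 0 of 38 in AD_ABR. Every Dct UMI of the class lay in 5 and 3 cells of cluster 27 in AD, and 0 cells of cluster 22, the rest of the class, carried any. The Dct fall therefore reflects these few cells and is not read as a change across Schwann-like cells. In Schwann-like cells 6 of 5013 genes fell and 0 rose by edgeR, with 406 at an unadjusted p below 0.05 and 15 lower by DESeq2. The 6 were 39 and 287 without AD replicate 1 and 2 and 12 and 27 without AD_ABR replicate 1 and 2.

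Over all cells summed, where a gene can move through the cell make-up, Zbtb16 rose from 26.0 ± 12.1 to 128 ± 8.88 CPM (SD, n = 2; log2 fold change 2.30 ± 0.34 SE, adjusted p = 0.042). The neutrophil-attracting chemokine gene Cxcl5 fell from 71.1 ± 3.23 to 3.56 ± 0.382 CPM (−4.32 ± 0.14 SE, adjusted p = 0.0088). Spp1, which encodes osteopontin, fell from 682 ± 378 to 29.3 ± 1.56 CPM (−4.54 ± 0.45 SE, adjusted p = 0.0245), and the hypertrophic cartilage gene Col10a1 by a log2 fold change of −7.09 (adjusted p = 0.0272). The lymphatic gene Ccl21a had a log2 fold change of −5.04 (adjusted p = 0.0387). Cell cycle genes fell as a list, 21 of 25 (23 adjusted over the list alone; median −2.33, camera adjusted p = 1.36e-49, and adjusted p = 0.452 with an estimated correlation), beside the lower share of proliferating cells. NF-kB targets fell, 11 of 20 (19 adjusted over the list alone; median −1.25, adjusted p = 2.03e-18, and 0.452 with an estimated correlation). The contractile list rose (median 1.15, adjusted p = 1e-12, and 0.564 with an estimated correlation), 19 of 20 members adjusted over the list alone and 0 over all genes. Of 20196 genes tested, 197 rose and 485 fell, with 6321 at an unadjusted p below 0.05 and 3703 changed by DESeq2. The 682 changed genes became 1227 and 5494 without AD replicate 1 and 2, and 0 and 0 by edgeR without AD_ABR replicate 1 or 2. Unnamed clusters tested by number gave 47 genes that rose and 80 that fell in cluster 2, 50 and 45 in cluster 5, 82 and 108 in cluster 14, and 1 and 2 in cluster 15 (2 and 2 with RLE size factors). In cluster 2, whose leading genes include Fmod and Hhip, Tsc22d3 (log2 fold change 1.89, adjusted p = 0.000876), Zbtb16 (1.80), Fkbp5 (1.69) and Klf15 (1.55) rose, and Ccl2 (−2.77) and Cxcl2 (−2.48, adjusted p = 2.31e-05) fell, both prone to free RNA at 0.027 and 0.0035 of their highest level elsewhere.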

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

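The tests of free RNA, dissociation, RNA quality, time of day, a single infiltrated library and tissue piece were chosen only after the results were seen, while the second glucocorticoid list was fixed before its values were seen. In 3 gene lists, the median and the mean level per library moved one way in 1 class or cluster and the opposite way in another, while single members went both ways. The differences between classes were not tested. Inflammasome and pyroptosis genes had a median log2 fold change of 0.33 in cluster 6, whose leading genes include Arg1 and Trem2, and −0.34 in smooth muscle-like cells. The mean level of the list in cluster 6 was 5.69 and 5.79 log2 CPM in AD and 6.28 and 6.05 in AD_ABR. MHC class II genes had a median of 2.73 in cluster 6 and −0.73 in smooth muscle-like cells. Their mean level was 7.35 and 7.85 log2 CPM in AD and 9.89 and 9.56 in AD_ABR in cluster 6, and 2.81 and 2.91 against 2.36 and 2.56 in smooth muscle-like cells, where all 9 members were prone to free RNA. Dissociation stress genes had a median of 0.48 in Schwann-like cells and −0.79 in endothelial-like cells.

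NF-kB targets were lower in AD_ABR in smooth muscle-like, endothelial-like and fibroblast-like cells, a call lost with an estimated correlation (adjusted p = 0.214, 0.136 and 0.267). Free RNA, the response to dissociation and RNA quality were weighed as explanations. Without members prone to free RNA the median was −0.85 (95% interval −1.21 to −0.64, 14 of 20 members left) in endothelial-like and −0.54 (−0.74 to −0.40, 15 of 20) in fibroblast-like cells, so free RNA of those members does not account for the lower values there. In smooth muscle-like cells only 4 of 20 members were left, with a median of −0.37 (−0.77 to 0.23), and free RNA could be the source. In fibroblast-like cells NF-kB targets lay below dissociation stress genes by 0.64 on the log2 scale (permutation p = 0.00166, and p = 0.0064 without members prone to free RNA). A response to dissociation that lowers both lists alike would not give this. As genes and not libraries were permuted, a response that lowers the lists unequally stays open. In endothelial-like cells the difference was 0.21 (permutation p = 0.253), and −0.01 without members prone to free RNA (permutation p = 0.997). The medians were then −0.85 for NF-kB targets and −0.86 for dissociation stress genes, so a difference in dissociation could explain the values. In smooth muscle-like cells the difference was 0.81 over all members (permutation p = 0.00128). Without members prone to free RNA it was 0.33 (permutation p = 0.371), with medians of −0.37 over only 4 NF-kB targets and −0.04 over 19 dissociation genes, too few to settle it. The lowest Rn18s-rs5 share of AD was 1.77 times the highest of AD_ABR, so RNA quality follows the groups and stays open as an explanation.

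Neutrophil-like, dendritic-like, T-like and B-like cells were smaller shares in AD_ABR. AD replicate 1 held the most neutrophil-like cells. In AD replicate 2 the neutrophil-like, B-like and dendritic-like shares were 9.56, 5.01 and 3.57 times the higher AD_ABR share. AD replicate 1 was thus not the only AD library with larger shares of these 3. The B-like and dendritic-like calls were lost without AD_ABR replicate 1 or replicate 2. Without AD replicate 1 the 3 shares were still lower by edgeR (largest adjusted p = 0.00827). That fit holds 1 AD library and cannot measure the spread within AD. How far AD replicate 1 accounts for these 3 therefore stays open. The T-like share was then 2.06 times the higher AD_ABR share, with an adjusted p of 0.0651, and 1 strongly infiltrated library could explain it. A different piece of tissue could also lower these shares, and the values it needs are there. The lowest AD share was 5.39 times the highest AD_ABR share for chondrocyte-like and 3.79 times for lymphatic endothelial-like cells. The latter class, led by Glycam1 and Ccl21a, depended on the clustering. It held 310 and 162 cells in AD and 37 and 26 in AD_ABR. At Leiden resolution 2 it held 146 and 103 in AD and 31 and 22 in AD_ABR. Mesothelial-like cells, which are not leukocytes either and were too few to test, numbered 0 and 1 in AD and 15 and 14 in AD_ABR. An anti-inflammatory effect of paquinimod and a difference in dissection therefore both remain possible.

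Klf15, Zbtb16, Fkbp5 and Tsc22d3 are known targets of the glucocorticoid receptor, and the genes that led to this reading had medians of 1.09, 1.46 and 1.35 in smooth muscle-like, endothelial-like and fibroblast-like cells. A response shared by other targets had been predicted to give medians above 0.3 in all 3 classes, and its absence medians under 0.1 in at least 2. The second list of targets had medians of 0.07 (95% interval −0.34 to 0.32), 0.05 (−0.21 to 0.29) and 0.40 (0.02 to 0.59) in the same classes. The prediction of a response was therefore not met, and 2 of the 3 medians lay on the side of its absence, though their intervals reached above 0.1. Elsewhere most medians were positive, at 0.41 in cluster 5, 0.39 in cluster 2 and 0.37 in Schwann-like cells. They were 0.28 in cluster 14, 0.26 in cluster 6 and 0.17 in cluster 15. Negative medians were seen in macrophage-like (−0.16) and dendritic-like cells (−0.06) and in cluster 10 (−0.05). Over all cells summed, where the cell make-up also counts, the median was 0.65. A general glucocorticoid response is not shown by these values, and a response limited to the genes first seen could not be tested on them. Clock genes of opposite phase differed by 0.25, −0.79 and 0.47, with a largest size of 0.79 and no common direction, so the time of collection could not be settled either.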

How the results depend on the processing

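The crossed pairing, leaving out genes prone to free RNA and the fits of unnamed clusters and of cluster 10 alone were chosen after seeing the data. In the order all cells, clusters 14, 15, 2, 5 and 6, dendritic-like, endothelial-like, fibroblast-like, macrophage-like and Schwann-like cells, smooth muscle-like cells and cluster 10, leaving out 1 library in turn gave these ranges of changed genes: 0 to 5494, 120 to 422, 10 to 272, 78 to 1464, 84 to 1568, 132 to 1572, 43 to 752, 67 to 1870, 136 to 525, 0 to 3475, 12 to 287, 1015 to 3181 and 197 to 799. In these fits a group has 1 library, which is assumed to vary like the other group. Counts of changed genes were the least stable results. Across all alternatives 64 counts stayed within 1.5 times the main count and 108 did not, and all 13 stayed within it with RLE size factors.

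Without the filter on low counts there were 2582 changed genes over all cells, 438 in cluster 14, 219 in 15, 432 in 2, 366 in 5, 1054 in 6 and 638 in 10. The same fit gave 538 in dendritic-like, 932 in endothelial-like, 1022 in fibroblast-like, 997 in macrophage-like and 80 in Schwann-like cells. DESeq2 gave 3703 over all cells, 88 in cluster 14, 50 in 15, 55 in 5 and 197 in 10, with 324 in endothelial-like, 302 in fibroblast-like, 209 in macrophage-like, 15 in Schwann-like and 1524 in smooth muscle-like cells. Leaving out genes prone to free RNA, which tests fewer genes, gave 72 in cluster 2, 59 in cluster 5, 85 in dendritic-like, 55 in fibroblast-like and 1 in macrophage-like cells. The cause was not tested for the other settings.

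With doublets kept the counts were 88 (dendritic-like), 225 (endothelial-like) and 283 (macrophage-like), and with a mitochondrial share under 10% they were 75 (dendritic-like), 51 (fibroblast-like) and 41 (macrophage-like). Leiden resolution 2 gave 81, 683 and 25 in dendritic-like, fibroblast-like and macrophage-like cells, resolution 0.5 gave 316 and 951 in the latter 2 and clustering without list genes gave 630 and 1000. With at least 500 genes per cell the macrophage-like count was 32. Classes from single-cell marker scores gave 324 (dendritic-like), 944 (endothelial-like), 1236 (fibroblast-like), 853 (macrophage-like) and 116 (Schwann-like). The classes did not hold the same cells in these settings. In the main setting the macrophage-like class held 1020 and 330 cells in AD and 317 and 708 in AD_ABR. At resolution 0.5 it held 1788 and 961 in AD and 450 and 967 in AD_ABR. How far this moved the counts was not tested.

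The labels give only a replicate number and do not say whether libraries of the same number were prepared together. Whether the numbers pair the libraries therefore stays open. The correlation of deviations between libraries of the same number was 0.34 in smooth muscle-like cells and −0.06 to 0.22 in the other classes and clusters. With the replicate number as a block the counts were 125 over all cells, 646 in cluster 14, 38 in 15, 513 in 2, 199 in 5 and 978 in 10. They were 525 in dendritic-like, 1345 in endothelial-like, 364 in fibroblast-like, 244 in macrophage-like and 60 in Schwann-like cells. S100a8 over all cells passed with the block (−5.79, adjusted p = 0.0426), 128 of 130 list calls were kept, and 33 named genes became significant while 12 no longer were. Over all cells the correlation was −0.11, and the crossed pairing gave 2685 changed genes there, with 10 in cluster 15, 280 in 5, 917 in 6, 44 in dendritic-like, 902 in endothelial-like, 225 in fibroblast-like, 37 in macrophage-like and 11 in Schwann-like cells.

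Without 1 library in turn, log2 fold changes of shares ran from −6.68 to −3.77 (neutrophil-like), −3.92 to −2.65 (B-like), −2.46 to −1.94 (dendritic-like), −3.27 to −2.24 (lymphatic endothelial-like), −2.82 to −2.31 (proliferating), −2.61 to −1.42 (T-like) and 0.67 to 1.81 (smooth muscle-like). They changed sign in endothelial-like (−0.80 to 0.36), fibroblast-like (−0.18 to 0.89, and −0.09 without AD_ABR replicate 2), macrophage-like (−1.03 to 0.70) and pericyte-like cells (−1.20 to 0.28), none of which had passed. S100a8 ran from −8.16 to −3.20 over all cells and −7.21 to −5.35 in macrophage-like cells, and S100a9 from −6.76 to −3.08 and −9.71 to −6.25. TMM factors over classes ended the calls for dendritic-like (−1.69), T-like (−1.48), lymphatic endothelial-like (−2.18) and proliferating cells (−2.06) and for clusters 15 and 6, and reversed endothelial-like (0.01) and macrophage-like cells (0.26). A mitochondrial share under 10% ended the call for proliferating cells (−1.69), and single-cell scores those for T-like (−2.09) and lymphatic endothelial-like cells (−1.98), with pericyte-like cells reversed (0.45). Fibroblast-like cells reversed at resolution 0.5 (−0.74). The cause was not tested.

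Of 58 lists past the test in the 6 classes, 0 passed with an estimated correlation. By fry 16 lists passed in these classes, counted whether or not they had passed camera. Of the 130 camera calls over all classes, clusters and all cells summed, 18 were kept by fry. Over all alternatives 686 list values kept direction and side of the threshold, 342 no longer passed and 10 reversed. Without AD replicate 2 the reversed values were NF-kB targets in cluster 15 (median 0.25, range over single libraries left out −1.16 to 0.25) and macrophage-like cells (−0.03, tested upward, range −0.43 to −0.03), and cytokines in macrophage-like cells (−0.28, tested upward, range −0.75 to −0.25). With doublets kept they were collagens (0.27) and interferon response (0.28) in macrophage-like and contractile genes in Schwann-like cells (0.14). With single-cell scores they were contractile genes in dendritic-like (0.09, tested downward) and Schwann-like cells (0.35) and interferon response in macrophage-like cells (0.30). The S100 list of cluster 10 reversed without AD_ABR replicate 1 (0.0, range −0.21 to 0.18). Among named genes 2709 values were unchanged in call, 217 gained and 184 lost it, and 3 reversed. Without AD replicate 1 these were S100a8, Endothelial-like (2.30, range −6.18 to 2.30), and S100a9, Endothelial-like (7.01, range −6.12 to 7.01). The latter passed in the opposite direction (adjusted p = 0.00192), from 29 UMIs in AD_ABR replicate 1, 96.6% of them in 1 cell. Sult1a1 in endothelial-like cells reversed with doublets kept (−0.02). The cause was not tested. Depth limits the Schwann-like class most, with sums as low as 0.162 × 1e+06 UMIs.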

Other observations

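The tests of cluster 10 alone were chosen only after the results were seen. Cluster 6, which was left unnamed because its leading genes mix macrophage and platelet markers, gained antigen presentation genes in AD_ABR. H2-Eb1, an MHC class II chain, rose from 677 ± 252 to 5393 ± 885 CPM (SD, n = 2; log2 fold change 2.99 ± 0.27 SE, adjusted p = 0.000396). Ciita, the master regulator of these genes, rose by a log2 fold change of 2.94 (adjusted p = 0.00491). Of 9 MHC class II genes 8 rose (median 2.73, adjusted p = 7.71e-34, and 0.489 with an estimated correlation). Ednrb, an endothelin receptor, fell from 112 ± 5.51 to 1.49 ± 1.45 CPM (−6.50 ± 0.38 SE, adjusted p = 6.11e-06). The hypoxia genes Vegfa (−2.65, adjusted p = 0.000396) and Hif1a (−1.96, adjusted p = 0.00115) and the matrix gene Fn1 (−2.99) fell. Of 20 glycolysis and hypoxia genes 6 fell (12 adjusted over the list alone; median −0.80, adjusted p = 7.69e-14, and 0.495 with an estimated correlation). Rn18s-rs5 moved with these genes (−1.85). In all, 247 genes rose and 282 fell, and these 529 became 1572 without AD replicate 2, 147 without AD_ABR replicate 1 and 132 without AD_ABR replicate 2.

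Cluster 10, the macrophage-like cluster led by Folr2, Cd163 and Lyve1, held most macrophage-like cells of AD_ABR. The interferon-induced gene Rsad2 fell from 1584 ± 0.262 to 281 ± 31.5 CPM (SD, n = 2; log2 fold change −2.50 ± 0.16 SE, adjusted p = 3.65e-06), Ifit1 by −2.38 and Ifit2 by −2.22. Of 22 interferon response genes 7 fell (12 adjusted over the list alone, with 1 that rose; median −0.85, adjusted p = 3.63e-17, and 0.261 with an estimated correlation). H2-Eb1 rose from 1493 ± 486 to 3978 ± 84.7 CPM (1.42 ± 0.21 SE, adjusted p = 0.00217), and 6 of 9 MHC class II genes rose (median 0.97, adjusted p = 1.96e-08, and 0.261 with an estimated correlation). Rn18s-rs5 fell as well (−1.24).

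Lower Idi1 and Insig1 in smooth muscle-like cells led to the hypothesis that the cholesterol synthesis pathway is lower there in AD_ABR. The prediction for pathway members not yet looked at was written before their values were seen. These 18 members had a median log2 fold change of −0.66 (95% interval −0.91 to −0.26), and 10 of them fell. The median was also negative in every other class and cluster tested (−0.83 to −0.18), where at most 4 members fell, and differences between classes were not tested. The camera p was 4.85e-10 at the preset correlation and 0.0849 with an estimated correlation. The values the hypothesis needs are there, while it was found and tested on the same libraries.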
